A study of Mus musculus with 3 samples.

How the data were processed

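RNA was measured by sequencing in the dentate gyrus, the hippocampal field made up mainly of granule neurons, dissected from adult C57BL/6 mice aged 8 weeks. The 3 libraries examined carry the group label E24 and the replicate numbers 1, 2 and 3, and each came from a separate animal, per the labels' protocols. The labels do not spell out what E24 stands for, nor the abbreviations WT and ECT that the table carries in its name. No second group was listed, so no comparison between conditions was made.

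The deposited values are RPKM, reads scaled to gene length and to the number of mapped reads, which the authors made with TopHat2 and Cufflinks on the mm9 mouse build, per the submitters' processing notes. Tool versions, the gene annotation and any filters are not given in the sources used here. The table holds 24458 rows, each with a gene symbol, an mm9 locus and 1 value per library. A further 9 value columns match none of the listed samples and entered no computation. The symbols number 23934, and 27 rows hold a date where a symbol would stand. Read depth is unknown, since the values are not whole reads, so no counting interval or detection floor is given. Coordinates are those of the table, in mm9. The reference annotation at hand is of another build and its coordinates were not used.

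Before any test, the order of values along the table was examined, because rows named for abundant genes were at 0 in all 3 libraries. For every row at 20 RPKM or more in one library, the share of rows in the other library with a value within a natural-log difference of 0.1 was computed at the same row and at each distance up to 100 rows. Distances of 26 to 100 rows gave the background. The share of matches in register was the excess at the same row over the excess within 10 rows on either side. On simulated libraries with 100%, 32.9% and 14.0% of values left in place, the estimate was 95.8%, 32.3% and 13.9%. Values turned out to be displaced along the table between libraries, so that at such rows not every library can follow the names. A value is therefore described as that of the row named for a gene, and a statement about the gene itself is not made from it.

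Quantities that do not need single rows in register were added after seeing the data. Distributions were taken over all rows. Regions were runs of about 100 consecutive rows on 1 chromosome, 242 in all, in the order of the table, where 29.4% of adjacent rows were out of genomic order, and their printed spans leave out the outer 5% of row positions on each side. Chromosomes were 1 to 19 and X. Gene family clusters were runs of 10 or more rows whose symbols share their leading letters, with 5 rows left out at each edge. The mean of log2(RPKM + 1) of each region, chromosome or family in each library, minus the mean of all rows on these chromosomes, was tested against 0 with limma 3.58.1 in R 4.3.3 (intercept-only model, moderated variance, two-sided, Benjamini-Hochberg, adjusted p under 0.05). Such a test asks whether the offset repeats between the libraries. It does not measure the spread among rows, nor whether a region, chromosome or family is unusual. The highest value within 5 rows of the rows of a gene list, the row itself included, was set against 10000 random lists of rows.

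Analyses fixed before the data were examined were run as designed and refer to row names. Values of rows sharing a symbol were summed. The level of each symbol was tested against 1 RPKM with limma on log2(RPKM + 1), one-sided, with a variance trend. Within-animal differences of 44 fixed gene pairs were tested with limma, two-sided, beside an exact sign-flip permutation test, whose smallest p with 3 animals is 0.25. For 33 gene lists, 18 of cell type or sex markers and 15 of functional groups, the median level was placed among 10000 random lists of equal size drawn from symbols with a mean of 0.1 RPKM or more. The spread between animals and the deviation of each library from the others used members at a mean of 1 RPKM or more and random lists matched on mean expression in 20 bins. On data simulated with an SD of 0.2 between libraries, limma recovered 100% of symbols set 2-fold above the level and 100% set 4-fold above it, among 23934 symbols, with 0 others called. With the spread each symbol has in these libraries it recovered 0% at either size. In these simulations a small random set of symbols lay above the level, whatever their real level, and all others below it. The data differ in this, with 4521 symbols called, so the 0% is not the recovery in the data. Among 44 pairs simulated with an SD of 0.2 it recovered 100% of 2-fold differences and called 2.32% of pairs without one. With each pair simulated at its own real SD, with a median of 1.84, it recovered 0.205% of 2-fold and 5.66% of 4-fold differences.

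The rule for named genes, fixed before the data were examined, took the 3 highest members of each list (all members of lists of up to 4), members at 0 in every library, all members of the pairs, the 10 symbols with the highest mean and the 10 with the largest spread among those at a mean of 5 RPKM or more. Since a row name does not identify the values of all libraries, only part of these are printed. Some items are not reported here. Symbols given for regions were chosen after their values were seen.

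Alternatives were a pseudocount of 0.1, upper-quartile scaling, quantile normalization, other filters on low values, the highest row per symbol in place of the sum, other levels and fold thresholds, limma without the variance trend, and leaving out each library in turn. For quantities added after seeing the data, the region size, the matching tolerance, the rows left out at cluster edges and the window around listed rows were also varied. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.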

Results

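The study examined how neuronal activation changes chromatin accessibility and RNA in the adult mouse dentate gyrus. The libraries analysed here form 1 group, E24, of 3 animals. Their values summed to 384523, 369261 and 350942 RPKM in replicates 1, 2 and 3, and read depth is unknown. With no second group, the data describe the RNA of this tissue under 1 label and the spread between its animals.

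The overall distribution of RNA levels differed little between the animals. Rows at 1 RPKM or more made up 49.7% ± 0.437 of the table (SD, n = 3), and those at 10 RPKM or more numbered 6102, 6136 and 6146. Rows at 100 RPKM or more numbered 642, 591 and 578. The median of rows at 1 RPKM or more was 10.2 RPKM ± 0.207 (SD, n = 3). The highest single value varied more, at 15096, 19979 and 11005 RPKM.

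Row by row, the same libraries differed widely. Of the 24458 rows, 7913 were at 1 RPKM or more in all 3 libraries, 8074 in none and 8471 in 1 or 2 of them. The row named for the splicing helicase Ddx5 had the highest mean, with 37.5, 19979 and 36.3 RPKM in the 3 libraries. The row named Smim4 had 15096, 0 and 0 RPKM, and that named for the proteasome subunit Psmd12 had 0.0398, 35.3 and 11005 RPKM. Across rows, which are not independent replicates, Pearson's r of log2(RPKM + 1) was 0.47, 0.49 and 0.58 for replicates 1 and 2, 1 and 3, and 2 and 3, with Spearman's rho of 0.563, 0.584 and 0.649.

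Matching values lay in neighbouring rows. For rows at 20 RPKM or more, a value within a natural-log difference of 0.1 stood at the same row of the other library in 16.2%, 15.2% and 43.2% of cases, against a background of 1.6%. Rows 1 to 10 positions away added 29.4%, 27.1% and 46.7% above background, so that 33.2%, 33.4% and 47.1% of the matches were in register. Averaging 10 neighbouring rows raised the lowest r to 0.91, and averaging 100 raised it to 0.99. Rows named for several abundant brain genes were also near 0. Those for the synaptic vesicle gene Syn1 and the activity-regulated gene Arc were listed at 0 in all 3 libraries, and that for the glycolytic enzyme gene Gapdh had 0, 0.0520 and 8.95 RPKM. The row for the actin gene Actb held 616, 731 and 745 RPKM. The row for the cyclophilin gene Ppia held 0.0824, 3.31 and 3.34 RPKM, with 1419, 1051 and 1007 RPKM within 5 rows of it. Within 5 rows of the Syn1 row the highest value was 0 in each library, and near the Arc row it was 9.18, 9.69 and 9.13 RPKM. Levels of single genes are therefore not stated, and an exact 0 is given only as listed.

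**Figure D1:**
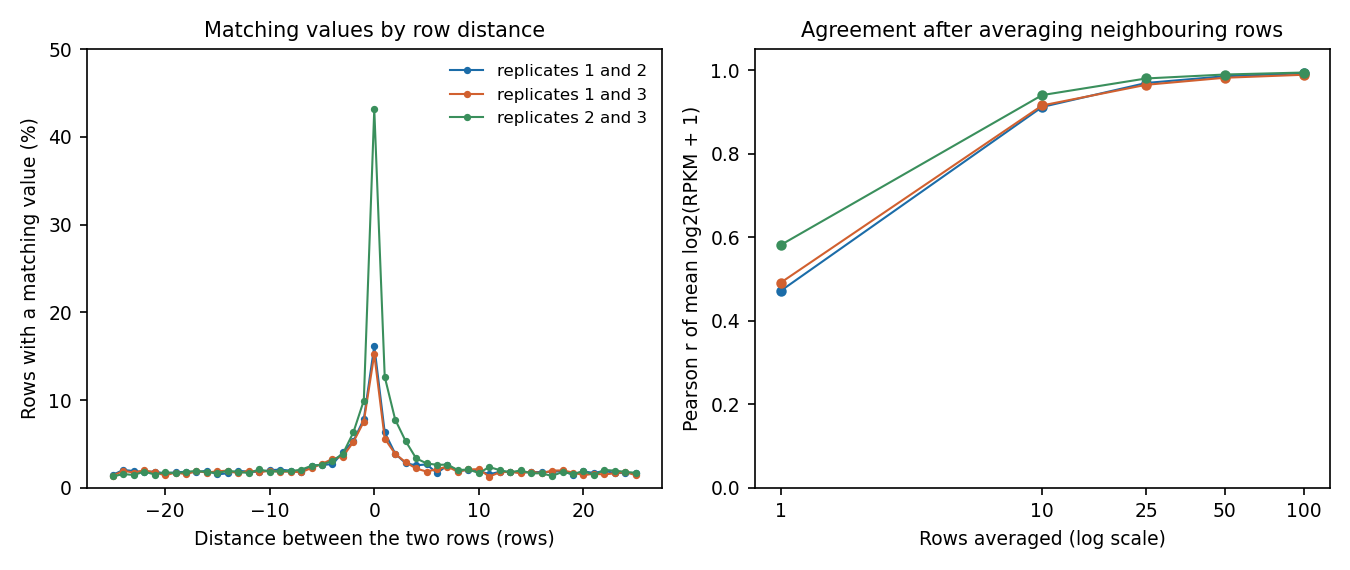
Left, share of rows at 20 RPKM or more (percent) that have a matching value in the other library, by distance in rows, for each pair of replicates; the peak at distance 0 reaches 16.2%, 15.2% and 43.2% and matches spread over the adjoining rows. Right, Pearson's r of mean log2(RPKM + 1) between replicates by the number of rows averaged (log axis), which rises from between 0.47 and 0.58 for single rows to 0.99 for 100 rows.

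Clustered gene families, many of them of other tissues, formed some of the lowest stretches of the genome. Odorant receptor clusters, whose genes serve olfactory sensory neurons, had 3.03% ± 0.556 of 681 rows at 1 RPKM or more (SD, n = 3), against 49.7% of the whole table. Vomeronasal receptor clusters, which serve pheromone detection, had 6.67% ± 1.15 of 100 rows at that level. No interior row of the late cornified envelope (Lce), kallikrein (Klk), prolactin (Prl) or reproductive homeobox (Rhox) clusters reached 1 RPKM in any library. Keratin clusters had 24.6% ± 3.04 of 19 rows and histone clusters 10.5% of 19 rows in every library. In all, 17 of 19 families lay below the mean of all rows and 0 above it (limma, adjusted p under 0.05). Clusters of bitter taste receptors (Tas) and major urinary proteins (Mup) were among the 17, with 6.06% ± 5.25 of 11 rows and 4.17% ± 3.61 of 16 rows at 1 RPKM or more (SD, n = 3). MicroRNA clusters had 1.65% ± 1.14 of 101 rows, at loci that are short for this assay.

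The clustered protocadherins on chromosome 18, adhesion genes of neurons, stood apart from the other families. Of their 49 rows, 68.7% ± 7.73 were at 1 RPKM or more (SD, n = 3), and their mean log2(RPKM + 1) was 2.21 ± 0.45. Their deviation from the mean of all rows, 0.32, did not pass (limma, adjusted p = 0.25). It passed without replicate 1, at 0.58 with an adjusted p of 0.0271 by limma, and with a pseudocount of 0.1, at an adjusted p of 0.0135. The natural killer receptor cluster Klra on chromosome 6 deviated by -0.85 with a limma adjusted p of 0.0532, and passed with upper-quartile scaling at 0.0420, with a pseudocount of 0.1 at 0.0225 and with 3 rows left out at each edge at 0.00541. The trace amine receptors (Taar) did not pass without replicate 1 or without replicate 3, nor the Serpinb cluster without replicate 1, with limma adjusted p of 0.0642, 0.0548 and 0.0642.

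**Figure D2:**
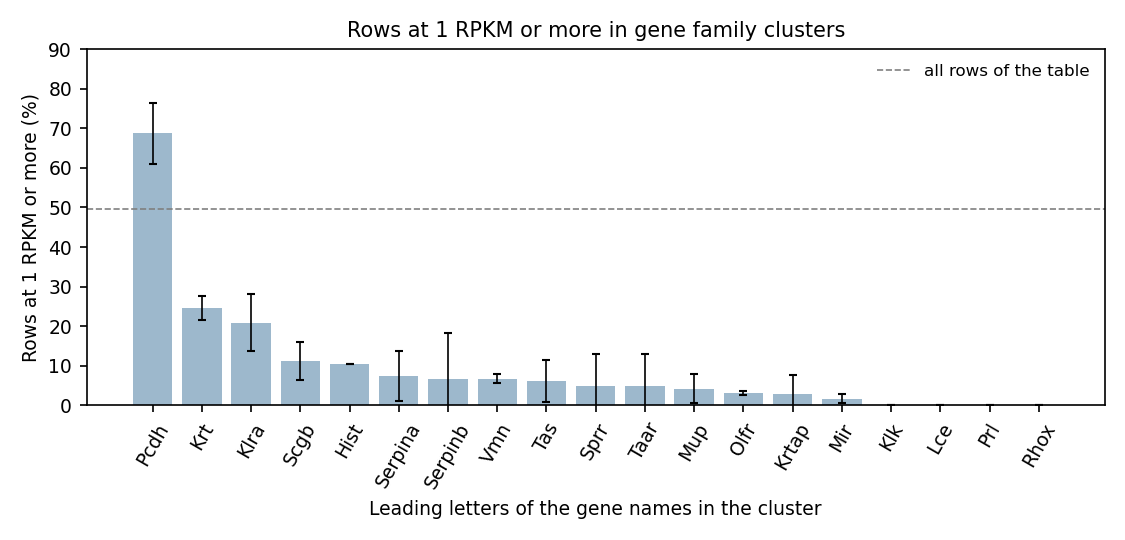
Share of rows at 1 RPKM or more (percent) in the interior of each gene family cluster, as mean and SD of 3 E24 libraries, with the share of all rows, 49.7%, as a dashed line. Protocadherins, at 68.7%, are the only family above that line, while odorant receptors stand at 3.03% and the Klk, Lce, Prl and Rhox clusters at 0.

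Regional levels were steady between animals and differed along the genome. Of 242 regions of about 100 rows, 123 lay above and 97 below the mean of all rows (limma, adjusted p under 0.05). These calls mean that an offset repeated between the libraries, not that a region stood out among regions. The median SD of a regional mean of log2(RPKM + 1) was 0.03 (n = 3). The lowest region, on chromosome 2 from 87789346 to 89892479 (mm9), held 97 odorant receptor rows and was listed at 0 throughout. The region from 85819468 to 87650956 on the same chromosome held 97 more and had a mean of 0.06 ± 0.03 (SD, n = 3). On chromosome X the region from 22796396 to 32967088 had a mean of 0.08 ± 0.10. Of the 12 lowest regions, 10 held at least 40 odorant receptor or 30 vomeronasal receptor rows.

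The highest regions lay on chromosomes 8, 5, 10 and 18, and the symbols given for them are landmarks chosen after the values were seen. The highest, on chromosome 8 from 69035638 to 73933803, had a mean of 3.15 ± 0.07 and 74.9% ± 0.55 of its rows at 1 RPKM or more (SD, n = 3). Its rows include those for the prohormone-processing enzyme Cpe, the perineuronal proteoglycan Ncan, the postsynaptic scaffold Homer3, the CREB coactivator Crtc1 and the vesicle GTPase Rab3a. The region on chromosome 5 from 124568697 to 135540536 had a mean of 2.95 ± 0.04. That on chromosome 10 from 78243240 to 80292035 had a mean of 2.92 ± 0.05 and includes the channel gene Hcn2 and the ribosomal gene Rps15. That on chromosome 18 from 24363844 to 36904241, which includes the activity-regulated transcription factor Egr1 and the kinase Camk4, had a mean of 2.84 ± 0.02. Which of the rows in a region carry its RNA was not resolved.

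**Figure D3:**
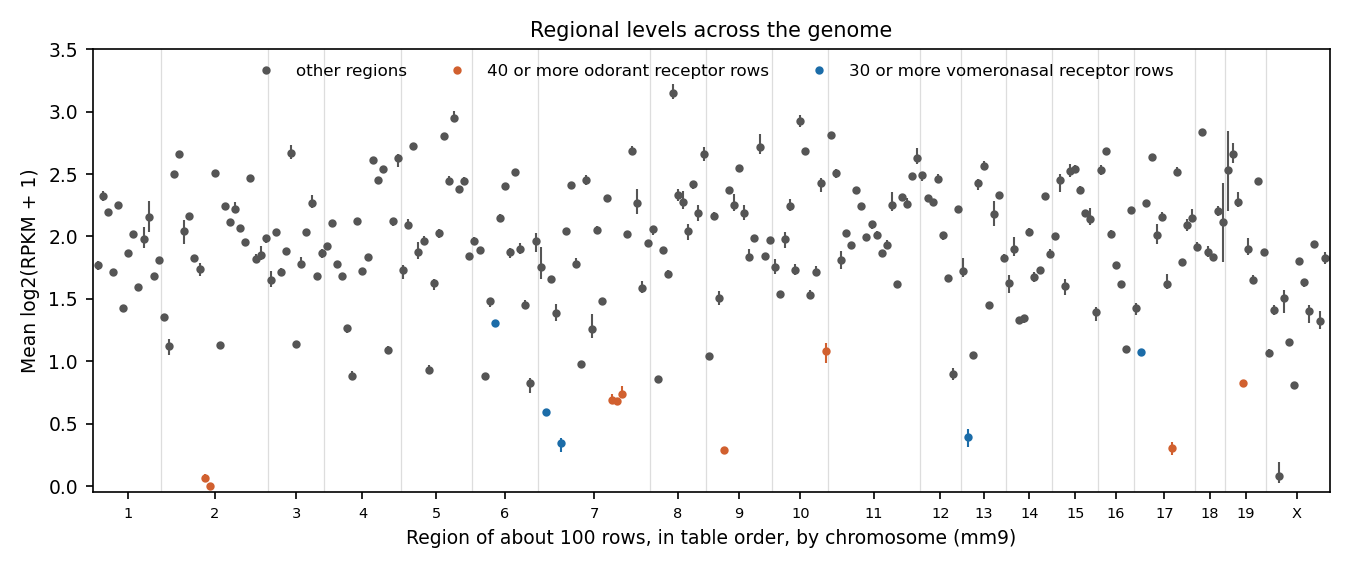
Mean log2(RPKM + 1) of 242 regions of about 100 rows in table order, as the mean of 3 E24 libraries with a line from the lowest to the highest library. Regions with 40 or more odorant receptor rows or 30 or more vomeronasal receptor rows are coloured and lie at or below 1.31, while the highest region, on chromosome 8, is at 3.15.

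Chromosome X had the lowest mean level of the 20 chromosomes. Its rows averaged 0.59 ± 0.02 below the autosomal rows in log2(RPKM + 1) (SD, n = 3), a difference of -0.59 that became -1.12 with a pseudocount of 0.1. On X 35.7% ± 0.425 of rows were at 1 RPKM or more, against 50.7% ± 0.477 on the autosomes. Among rows at that level the X median was 0.913 ± 0.014 times the autosomal median. Against the mean of all rows, 12 chromosomes were higher and 7 lower (limma, adjusted p under 0.05), and X deviated by -0.56 with an adjusted p of 1.3e-06. Chromosome 11 deviated by 0.29 and chromosomes 8 and 15 by 0.25, and with a pseudocount of 0.1 chromosome 18 was highest at 0.51. Chromosome 7, which carries many receptor clusters, deviated by -0.29. Chromosome 3 did not pass at -0.01 (limma adjusted p = 0.327), and with a pseudocount of 0.1 it was higher by 0.05 with a limma adjusted p of 0.000553. Calls on chromosomes 1 and 9 were lost without replicate 2 and without replicate 3. The SD between animals was largest on chromosome 19, at 0.07.

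**Figure D4:**
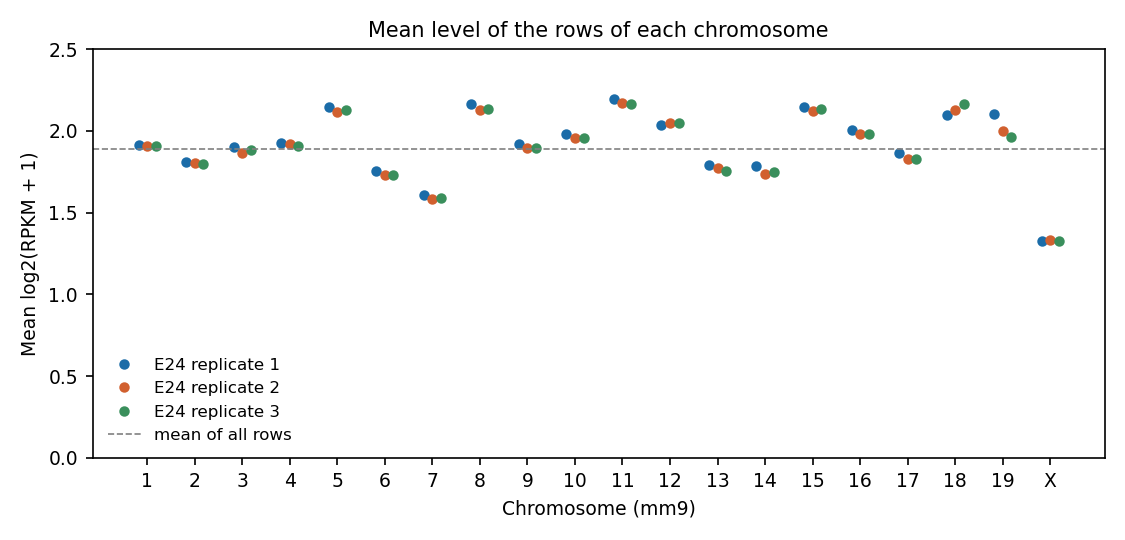
Mean log2(RPKM + 1) of the rows of each chromosome in each of the 3 E24 libraries, with the mean of all rows, 1.89, as a dashed line. Chromosome X is lowest at 1.33, chromosome 7 next at 1.60, and chromosome 11 highest at 2.18.

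By row name, 4521 of 23934 symbols lay above 1 RPKM (limma, adjusted p under 0.05), and without replicate 3 the number was 2686. Of the 347 listed symbols, 102 passed and 17 were listed at 0 in every library. Chromatin remodelling rows had 11 of 16 members above 1 RPKM, or 12 adjusted over the list alone, and the highest median level of the lists at 4.56, above 99.99% of random lists. Among them the helicase rows Chd3 and Chd8 held 107 and 102 RPKM on average, and Chd4 held 316, 16.1 and 37.5 RPKM. GABA-A receptor rows had 7 of 12 members above 1 RPKM, or 8 adjusted over the list alone. Microglial rows had 8 of 12, or 9 adjusted over the list alone, including the complement row C1qa at 25.7 ± 3.30 and the protease row Ctss at 26.5 ± 2.82 RPKM, while the Csf1r row was listed at 0. Voltage-gated channel rows had 10 of 28 (14 adjusted over the list alone) and late activity-response rows 6 of 17 (7 adjusted over the list alone). These 5 lists lay above the 95th percentile of random lists. Several GABA-A rows, such as Gabra2, Gabra4, Gabrb1 and Gabrg1, and the microglial rows C1qa, C1qb and C1qc lie near each other. The random lists were not matched for this. Late activity-response rows fell to the 89.37th percentile without replicate 3, and voltage-gated channel rows to the 93.72nd without replicate 1. Neural progenitor rows lay below the 5th, and at the 20.4th among random lists drawn without a filter, with 1 of 10 members above 1 RPKM on either adjustment. Any of these values may carry the displacement described above, and which of them do was not resolved.

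Immediate early rows had 6 of 21 members above 1 RPKM, or 8 adjusted over the list alone. The Jun row held 63.5, 96.3 and 85.3 RPKM, the Npas4 row 66.4, 51.7 and 1.18 RPKM, and the Fos row 0.0323, 6.13 and 0 RPKM. The row of the neuritin gene Nrn1 held 309.8, 298.6 and 322.9 RPKM. The granule neuron rows had 3 of 16 members above 1 RPKM, or 6 adjusted over the list alone. Their Calb1 row held 7.18, 91.3 and 89.8 RPKM, and the Prox1 row 1.58, 39.3 and 0 RPKM. Synapse rows had 4 of 14 on either adjustment, and the Snap25 row held 8.70, 8.09 and 612 RPKM.

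None of the 44 fixed pairs of rows differed within animals by limma (0 at an adjusted p under 0.05, 10 at an unadjusted p under 0.05). The lowest adjusted p was 0.18. The exact sign-flip permutation test could not go below 0.25 with 3 animals. The same sign was seen in all 3 animals for 20 of the 44 pairs, a larger share than the 25% that chance gives. Some rows enter several pairs, and this share was not tested. The glutamate receptor rows Gria2 and Gria1 differed by 3.59 on the log2(RPKM + 1) scale with an SE of 0.73, and Egr1 and Egr2 by 2.62 with an SE of 0.59. The median SD of a pair difference was 1.84. With each pair simulated at its own SD, 5.66% of 4-fold differences were recovered.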

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

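Settings for register, regions, chromosomes and families, and windows of 2 and 10 rows, were chosen after seeing the data; the others were fixed before. Of 96 alternatives for the main results, 78 stayed within 1.5 times the count or 1 SD, and 18 moved. The count of symbols above 1 RPKM was 2049 at a level of 5 RPKM, and 2686 to 4978 with a library left out. The numbers of regions that differed were 423 and 110 with 50 and 200 rows per region, where 489 and 121 were tested. Lists below the 5th percentile numbered 2 with a pseudocount of 0.1, 7 with a stricter filter and 0 without a filter, and 1 to 4 with a library left out. Library deviations of lists numbered 5 with a stricter filter and 0 to 4 with a library left out, and lists of unusual spread 5 and 0 to 2. Mean row agreement was 0.34 on rows at 0.1 RPKM or more and 0.47 to 0.58 with a library left out, against 0.51. Agreement of region means was 0.92, 0.97 and 0.99 with 10, 25 and 50 rows. The X difference was -1.12 with a pseudocount of 0.1. Apart from settings that change what is tested or leave out a library, the cause was not tested. Of 297 list medians under alternatives, 31 moved by over 1 SD, 15 of them with the pseudocount and 16 with a library left out. Row agreement is taken across rows, so the highest row per symbol leaves it as it is. Between groups, no paired analysis was possible because the samples form 1 group. Depth is unknown, so what it limits could not be stated.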

Other observations

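Astrocyte rows had 3 of 12 members above 1 RPKM by limma, with the Gfap row at 1.11, 198.9 and 186.5 RPKM, and oligodendrocyte rows 1 of 11, with the Cnp row at 40.1, 25.1 and 49.9 RPKM. Oligodendrocyte precursor, GABAergic interneuron and CA3 pyramidal rows had 3 of 8, 3 of 12 and 3 of 8, and CA1 pyramidal rows 2 of 8. Mossy cell, immature granule neuron, endothelial, choroid plexus and red blood cell rows each had 1 member above that level, and mural and meningeal fibroblast rows 0. Histone deacetylase rows had 6 of 11, with Hdac2 at 109.1, 61.8 and 62.7 RPKM, ionotropic glutamate receptor rows 6 of 15 and metabotropic ones 4 of 8. DNA methylation rows had 4 of 17, CREB, MEF2 and SRF rows 3 of 15, AP-1 rows 2 of 10, reference rows 3 of 10, neuropeptide rows 1 of 15 and neurotrophin rows 0 of 8. Adjusted over the list alone, the counts were 0 for neuropeptide, 2 for immature granule neuron, 4 for CREB, MEF2 and SRF, 5 for DNA methylation, and 7 each for histone deacetylase and ionotropic glutamate receptor rows, and the other lists of this paragraph so far gave equal numbers. The Xist row held 8.50 ± 2.18 RPKM, and of the Y-linked rows Eif2s3y held 13.6 ± 2.42 and Kdm5d 3.74 ± 0.32 RPKM (SD, n = 3), while Ddx3y and Uty were listed at 0. In single libraries, 3 of 93 list deviations lay in the outer 5% of random lists, a share below the 5% that chance gives. They were those of immature granule neuron rows in replicate 2 and meningeal fibroblast rows in replicates 2 and 3. By row name, lists of low spread between libraries, below the 5th percentile, were neural progenitor, microglia and chromatin remodelling, 3 in all. Displaced values enter the SD of a row, so this spread does not measure variation between animals alone. Without replicate 1, 2 or 3 the number of such lists was 2, 1 and 0.

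The tests of row order, of abundant rows against depth, of misplaced names and of reference rows were chosen after the results they measure were seen; those of windows of 5 rows around listed rows were written before, and windows of 2 and 10 rows were added later. The first pattern is the low agreement of single rows between libraries. Sparse reads as the only cause were argued against for high rows. At least 20.1% of the rows at 100 RPKM or more in one library were under 1 RPKM in another. The share was at least 19.0% without rows within 10 positions of a locus under 250 bp, where few reads make a high RPKM. Displaced values give such rows at any depth, so whether sparse reads add to the low agreement was not settled. Values were displaced along the table between libraries, as described above, and how much of the low agreement this accounts for was not measured. Matching values 1 to 10 rows away exceeded the background by at least 27.1% of rows in each pair of libraries. The step at which the order changed was not tested, and no biological explanation was tested, since there is 1 group.

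The second pattern is that rows named for abundant brain genes were near 0. Displacement by up to 5 rows stays open. The highest values near reference and synapse rows together lay above only 92.3% of random lists of rows in the lowest library. That is between the bounds set for either outcome, with 98.33% for 2 rows on each side and 90.31% for 10. Reference rows alone lay at the 99.24th to the 99.9th percentile, and synapse rows lower. The listed row counts in its own window, so high rows such as Actb raise these percentiles without any displacement. A lack of neurons would leave genes used by cells of every type, so it would not account for low reference rows. At least 3 of the 10 reference rows were under 1 RPKM in each library. Those rows belong to the pattern itself and their names may not identify their values, so the count does not test the tissue. For synapse rows a lack of neurons stays open at the 20.4th to the 92.36th percentile within 5 rows. Rows of neuronal receptors, channels and synapses together lay at the 99.3rd, 88.1st and 99.5th percentile by their own values. A different order of names and values was not settled by the bound set for it. Rows named over 50 positions from their genomic rank in silent stretches numbered 68, 72 and 70. They were at 1 RPKM or more in 29.4%, 23.6% and 25.7% of cases, around the bound of 25%. Their neighbours were at that level in 15.88%, 16.15% and 17.05% of cases, a lower share in each library. A different order throughout would give such rows the level of their neighbours, so these shares argue against it for these rows. The difference was not tested, and a partly different order stays open. Of adjacent rows on 1 chromosome, 29.4% were themselves out of genomic order. Isolated rows of loci under 250 bp were at 0 in 41.1%, 51.4% and 47.5% of cases, against 21.0%, 23.7% and 23.4% of rows 5 to 10 positions away, so names and values shared part of their order.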
